A study of Ruditapes philippinarum with 2 samples.

How the data were processed

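The study sequenced total RNA from the posterior adductor muscle of Manila clams, extracted with RNeasy columns and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. Each library was a pool of animals. The deposited table holds raw read counts for 47339 assembled contigs in 2 columns, 1 per library. BWA 0.7.12 and SAMtools 1.1 are named in the submitters' processing notes, with no role given. How the reference contigs were assembled and named is not given in the sources used here. Such steps matter here, since reads of alleles or paralogs are split over contigs by the aligner, and a contig assembled from the animals of one pool takes that pool's reads more easily.

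Every deposited count was even, as when both mates of a pair are counted. Intervals and floors were therefore computed on pairs, a choice made after seeing the values, and single reads were tried as an alternative. The columns name the health state in French, and each was matched to the sample with that state in its title. The planned directions were by pool code. Because the sample labels and the design text assign the codes to opposite states, and the columns carry no code, directions were written by health state. Expression values were not used to settle this.

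Codes in contig names were read as UniProt entry mnemonics, which no file header states. Code meanings are background only. The prefix PMAR is that of locus tags of the Perkinsus marinus genome. Of the 9447 codes, 4 matched symbols of the reference gene table for assembly ASM2657151v2, so that table was not used for names, and no coordinates are given.

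Counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, to effective sizes of 111037333 reads (diseased) and 253335614 reads (healthy), and divided by these sizes to give CPM. Ratios have exact Clopper-Pearson 95% intervals from the split of a contig's pairs between the libraries. A contig without reads in a library was set to a floor of 3 pairs, worth 0.054 CPM in the diseased and 0.0237 CPM in the healthy library. Its ratio is a value against that floor, and its interval is open on one side. All 47339 contigs passed the minimum of 20 reads, the smallest sum being 24. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

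The rule, lists and alternatives were set before the data were examined. The 21 lists were written as patterns on descriptions and translated by hand into codes once the contig names, and the counts of a few contigs, had been seen, but before any ratio per list was computed. Each list's median was ranked among 10000 random lists drawn with replacement in 20 bins of mean log2 CPM, with a pseudocount of 0.5 CPM. Named contigs were the 12 in each direction with the largest interval bound nearest to equality, at least 100 reads in the higher library and an informative code, 1 per code, plus the 3 most abundant of each list and of each library; for lists, examples from these 3 are printed. Some contigs that the rule took are not reported here. Codes that are locus tags, PMAR included, were not taken as informative. Alternatives were other scalings (total counts, upper quartile, and median of ratios from DESeq2 1.42.0), other minimums and folds, no interval, and thinning. Sums per code, subsets of contigs and random lists from named contigs were added after seeing the data.

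The rule was tested on simulated pair counts for 47339 contigs in the diseased over healthy comparison, with 50 contigs changed at each of 4 sizes. All 50 at a log2 change of 2.5, 3.5 and 5.0 were called, 0 at 1.5, which is under the rule, and 0 unchanged contigs. Intervals of unchanged contigs covered 0 in 95.0% of cases. The simulated counts varied by Poisson counting error only, around a profile shared by both libraries, and were scaled by total counts. They therefore say nothing on differences between animals, alleles or reference contigs. No column of values was left out.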

Results

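Brown Muscle Disease affects the posterior adductor, the muscle that closes the shell of the Manila clam. Total RNA of that muscle was pooled from 5 wild clams into 2 libraries, 1 from animals with signs of the disease and 1 from animals without. The diseased library held 137237872 counted reads and the healthy library 204970470, over 47339 assembled contigs. Names were attached to 15848 contigs, under 9447 distinct codes, and the other 31491 carried only a number. With 1 library for each state no difference has a replicate check, and no p-value is given. Intervals are exact 95% intervals and cover counting error only.

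The labels contradict each other on the pools. The sample labels give the healthy state to the pool coded SURF+ of 3 animals and the diseased state to the pool coded BUR- of 2 animals. The study's design text gives signs of disease to SURF+ and none to BUR-. The columns of the count table name only the health state, so directions are written here as the library labelled diseased against the library labelled healthy. Were the states of the libraries exchanged, every direction would turn.

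The first question was which transcripts differed between diseased and healthy muscle. Among named contigs, the excess in the diseased library with the largest lower bound was in KCP.3.12, at 264 CPM (read counts scaled to the effective library size) against 0.0237, a log2 ratio of 13.44 (interval 11.90 to 15.72). LYS3.3.4, named for a lysozyme, an enzyme that cuts bacterial cell walls, reached 229 CPM against 0.0316 (log2 ratio 12.82, interval 11.47 to 14.70). PIF.2.9, named for a shell matrix protein, stood at 1078 CPM against 1.16 (log2 ratio 9.86, interval 9.63 to 10.10). CSRP3.2.3, named for a muscle LIM protein, stood at 141 CPM against 0.0947 (log2 ratio 10.54, interval 9.73 to 11.49). Further contigs named by the size rule in this direction were LYS.2.15, SVEP1.12.61, CRIM1.1.3 and HAAF.3.12, with log2 ratios from 10.13 to 12.04. TRPA1.2.8, TREX2.1.1 and ASL1.1.4 had no read in the healthy library. Against a floor of 3 read pairs they were 3228-fold, 1290-fold and 898-fold higher in the diseased one. The lower interval bounds were 2624-fold, 1048-fold and 729-fold.

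In the other direction, antimicrobial peptide names were among the contigs named by the rule. DEFI.1.1, named for a defensin, had 287 CPM against 0.324 (log2 ratio -9.79, interval -10.54 to -9.13). BDEF.1.4, named for a big defensin, had 35.8 CPM against 0.018, which was 1 read pair (log2 ratio -10.96, interval -16.26 to -8.48). MYS.8.12, named for a myosin heavy chain, had 399 CPM against 0.829 (log2 ratio -8.91, interval -9.36 to -8.49). LYS.8.15, HAAF.9.12, THRB.13.13, PKS16.1.1, RN213.4.11 and MUC2.1.3 had log2 ratios between -10.69 and -9.34. RN213.4.11 and MUC2.1.3 also rested on 1 read pair in the diseased library, under the floor given to contigs without reads. Their intervals were -15.99 to -8.21 and -15.93 to -8.14. CNR11.4.4, NCAN.9.9 and ASGR2.1.2 had no read in the diseased library. Against the same floor they were 1241-fold, 476-fold and 445-fold higher in the healthy one, with lower interval bounds of 1009-fold, 387-fold and 361-fold.

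Several of these contigs were 1 of many under their code, and sums of reads over a code often lay nearer to 0. The summed log2 ratio was 0.99 for KCP, 1.03 for LYS, 0.59 for both SVEP1 and HAAF, 0.15 for ASL1, 1.76 for TRPA1 and -0.62 for MYS. It was -0.97 for THRB, -1.80 for RN213, 0.73 for NCAN and 1.27 for CNR11. CSRP3, CRIM1 and MUC2 summed to 2.48, 2.15 and -3.70. The values for SVEP1, HAAF and ASL1 changed sign when total counts replaced the TMM factors. LYS and HAAF each had a contig among the most extreme in both directions. Among codes with several contigs, sums far from 0 were those of LYS3 (10.22), PIF (6.96), BDEF (-9.42) and ASGR2 (-4.14). Contigs under 1 code can be alleles, paralogs or pieces of a transcript, so single contig ratios are uncertain.

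**Figure D1:**
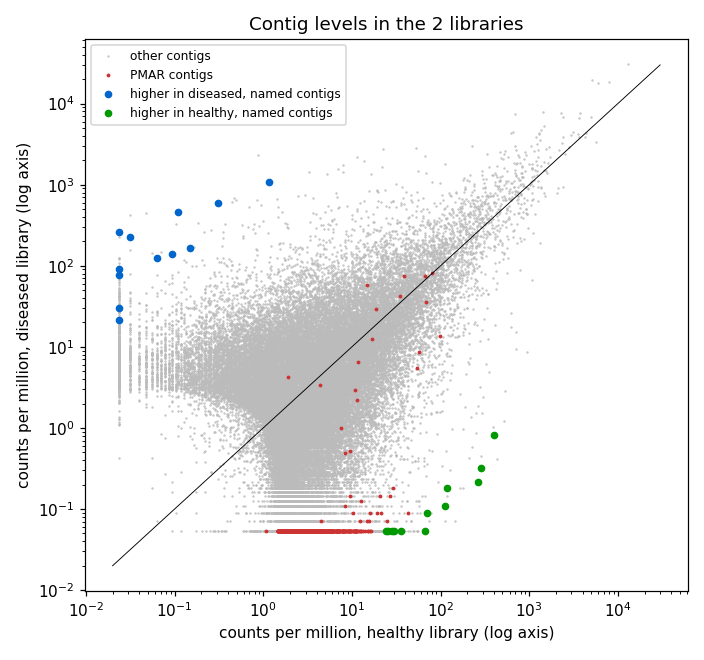
Each point is a contig, with its CPM in the healthy library on the horizontal log axis and in the diseased library on the vertical log axis. Contigs under 3 read pairs in a library are drawn at that floor; blue and green mark the 12 contigs that the size rule took in each direction and red the 867 contigs with the PMAR prefix, of which 480 had no read in the diseased library.

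By the fixed rule of at least 4-fold, 20 reads and an interval clear of equality, 10630 contigs were higher in the diseased library and 13233 in the healthy one, while 23476 met neither. The healthy side held 55.5% of these calls with TMM factors and 66.8% with total counts only. The median log2 ratio of all contigs was -0.29, and total counts moved it by -0.61. Ratios and list medians between 0 and 0.61 therefore changed sign under total counts. With at least 20 reads in one library and 0 in the other, 285 contigs were seen in the diseased library only and 2049 in the healthy library only. Most of the 285 were unnamed contigs numbered up to 16920. Most of the 2049 were unnamed contigs numbered after it, and a further 480 had the PMAR prefix.

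The direction followed the numbering of the contigs. Of the 12150 unnamed contigs numbered up to 16920, 8223 were higher in the diseased library and 27 in the healthy one, with a median log2 ratio of 2.81. Of the 19341 numbered after it, 378 were higher in the diseased library and 8926 in the healthy one, with a median of -1.77. The break was located on the ratios themselves. Among named contigs without the PMAR prefix, 2029 were higher in the diseased library and 3425 in the healthy one. Summing reads per code left 637 codes higher in the diseased library and 2311 in the healthy one, or 1473 without PMAR.

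**Figure D2:**
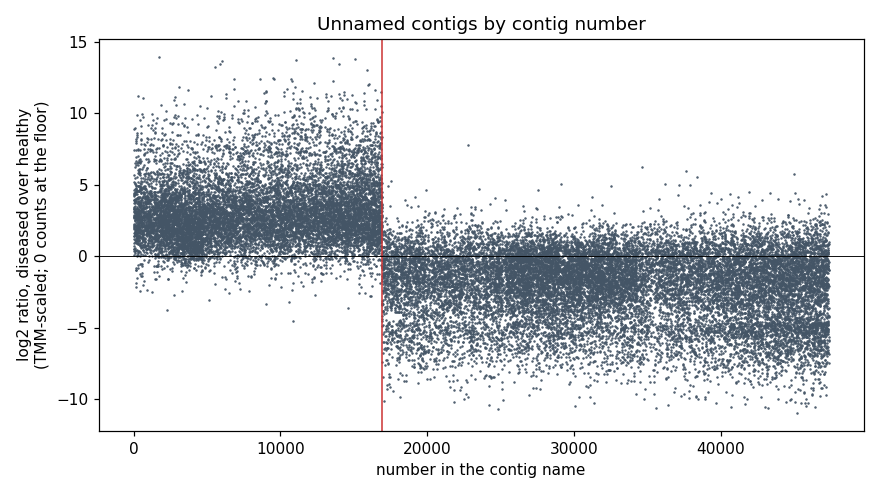
Each point is an unnamed contig, with the number in its name on the horizontal axis and its log2 ratio of the diseased over the healthy library on the vertical axis. The red line marks number 16920, where the median goes from 2.81 to -1.77.

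Mitochondrial and contractile names led both libraries. CYB.6.7, named for mitochondrial cytochrome b, led with 30822 CPM in the diseased and 13053 CPM in the healthy library. ACT.1.9, named for actin, had 19294 and 5064 CPM (log2 ratio 1.93). MYSP.18.18, named for paramyosin, the core protein of molluscan thick filaments, had 18152 and 5992 CPM (log2 ratio 1.60). The unnamed contig_015942 was the remaining leader, at 18269 and 7936 CPM. The 10 most abundant contigs took 10.6% of reads in the diseased library (exact interval 10.55 to 10.57) and 7.25% in the healthy one (7.247 to 7.257). The top 100 took 28.5% and 22.6%, and the top 1000 took 60.1% and 53.9%.

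The contractile list had a median log2 ratio of -0.07 over 181 contigs, at percentile 0.35 of 10000 random lists matched on expression. Of its contigs, 20 were higher in the diseased library, 43 in the healthy one and 118 met neither rule. Its summed reads went the other way, at a log2 ratio of 0.82, carried by actin and paramyosin. TPM.2.4, for tropomyosin, had a log2 ratio of 0.45. Against random lists of named contigs only the list stood at percentile 5.72, and per code at 68.6. Muscle energy metabolism had a median of -0.32 over 42 contigs (percentile 0.54), with 8 higher in each library, and its sum was 0.49. ENO.1.1, the glycolytic enzyme enolase, had 516 CPM against 261, and KARG.1.2, for arginine kinase, had 234 against 254, a log2 ratio of -0.12 that became 0.45 summed per code. Per code the list stood at percentile 73.4.

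Respiratory chain contigs had a median of 0.50 (165 contigs, percentile 76.5, or 98.5 against named contigs and 67.0 per code), with 18 higher in the diseased and 10 in the healthy library. Their most abundant members after cytochrome b, NU1M.2.2 and COX1.1.8, had log2 ratios of 1.47 and 1.78. Ribosomal protein contigs had a median of 0.78 over 387 contigs, above all 10000 random lists. Of these, 64 were higher in the diseased library and 18 in the healthy one. RL5.1.3, RL10.4.4 and RSSA.1.7 had log2 ratios of 0.81, 0.57 and 0.40. Per code the list stood at percentile 99.7. The reference genes, a list that shares small-subunit ribosomal proteins with the former, had a median of 0.73 (181 contigs, percentile 99.9), and EF1A.5.8 a ratio of 0.48. Per code they stood at percentile 76.1. Ribosomal proteins took 8.12% of all reads in the diseased library and 7.87% in the healthy one, and reference genes 5.12% and 5.29%. Before scaling, the summed reads of both lists thus differed little.

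Pattern recognition and humoral immunity spread widely. Its 349 contigs had a median of -0.66 (percentile 0.05, but 64.1 against named contigs) and quartiles of -4.87 and 1.80, with 79 higher in the diseased library, 137 in the healthy one and 133 in neither. The summed reads had a log2 ratio of 0.51 and the codes stood at percentile 90.8. CO3.9.10, for complement component 3, had 88.6 CPM against 780 (log2 ratio -3.14, interval -3.18 to -3.10), while CO3.3.10 had a log2 ratio of -0.35. Immune signalling (51 contigs, median 0.25, percentile 60.8), antiviral response (104 contigs, median 0.04, percentile 45.8) and apoptosis (140 contigs, median 0.27, percentile 86.5) lay within the random lists. Against named contigs, antiviral response stood at percentile 99.1 and apoptosis above all random lists. Per code, the percentiles were 67.6 for immune signalling, 20.7 for antiviral response and 93.6 for apoptosis, and 1 antiviral code was higher in the diseased library against 7 in the healthy one. LITAF.4.4, IFI44.1.20 and BIRC2.4.7 had log2 ratios of 1.14, 1.64 and -0.19. The other antiviral contigs taken by the rule, both under the code IF44L, went the other way from IFI44.1.20. Their log2 ratios were -0.38 and -0.82, while their code summed to 0.26.

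Viral, retroviral and transposable sequences were lower in the diseased library as a list. The median was -1.50 over 317 contigs, below all random lists, with 48 higher in the diseased library and 126 in the healthy one. POL.1.16, RTBS.20.48 and TCB1.5.9 had log2 ratios of -1.45, -1.10 and -0.97, the last becoming 0.43 summed per code. The summed reads gave -0.65, and the codes stood at percentile 0.01. Heat shock and folding names had a median of -0.45 over 129 contigs (percentile 0.11, or 15.1 against named contigs) and stood at percentile 0.29 per code. CRYAB.1.1, named for a small heat shock protein, had 192 CPM against 731, and HS90B.1.2 had 796 against 1476, whereas HSP7C.1.2 had a log2 ratio of 0.57.

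The oxidative stress, iron and detoxification list had a median of 0.54 (192 contigs, percentile 97.0), with 48 higher in the diseased library and 23 in the healthy one. Per code, and against named contigs, it lay above all random lists. Its leading contig, FRIS.11.11, for the iron store ferritin, had 3870 CPM against 2377. Lysosomal and autophagy proteases had a median of 0.62 (60 contigs, percentile 88.8, or 99.6 against named contigs and 96.3 per code). CATL1.1.9, for cathepsin L, had 786 CPM against 126 (log2 ratio 2.64, interval 2.61 to 2.66). Ubiquitin and proteasome names had a median of -0.38 (213 contigs, percentile 0.00, or 6.38 against named contigs, codes at 22.2), with 9 higher in the diseased library and 41 in the healthy one. RS27A.1.4 and RS27A.4.4 had log2 ratios of 1.03 and -0.63, and their code summed to 0.46.

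Extracellular matrix names went both ways. The median of 138 contigs was -0.83 (percentile 0.03), with 31 higher in the diseased library and 51 in the healthy one, yet the summed reads had a log2 ratio of 1.62. CO1A1.1.1, named for a fibrillar collagen, had 7374 CPM against 690 (log2 ratio 3.42, interval 3.41 to 3.43). CO6A4.1.1, for a type VI collagen, had 290 against 961 (log2 ratio -1.73). Calcium handling had a median of -0.67 (67 contigs, percentile 1.35), and its leading contig RY44.1.3, for the ryanodine receptor, had 595 CPM against 877. RY44.3.3 had 214 CPM against 877, and the code RY44 summed to a log2 ratio of -1.12. These lists stood at percentiles 7.24 and 20.5 against named contigs, and at 21.0 and 48.2 per code. Cell cycle names had a median of -0.33 (51 contigs, percentile 16.7), with H33.1.2 at 1.65 and H1D.1.1 at -2.69.

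Markers of other cell types lay within the random lists by median. Haemocyte markers stood at 0.24 (32 contigs, percentile 45.5), gonad markers at -0.08 (36 contigs, percentile 38.7), and the joint list for digestive gland, mantle, nerve and ciliated cells at -0.22 (129 contigs, percentile 12.3). Their summed reads had log2 ratios of 0.95, 1.36 and 0.67, the latter pair opposite in sign to the medians. The leading contigs of these 3 lists, TYB12.1.1, DDX4.1.1 and TBA1.3.3, had log2 ratios of 1.14, -0.29 and 0.37. TBA1.3.3, for a tubulin, is also among the reference genes. The next gonad marker, VMO1.1.19, had a log2 ratio of 3.79. Its code VMO1, with 19 contigs and a summed log2 ratio of 1.96, carried most of the gonad sum. It held 811.6 of the 924.1 CPM of gonad markers in the diseased library. Per code, 0 gonad markers were higher in the diseased library, 3 were higher in the healthy one and 10 met neither rule. In lists added after seeing the data, summed reads of shell matrix names were 22.7-fold and those of digestive enzymes 6.70-fold higher in the diseased library. The 11 shell codes with 1000 reads or more had a median summed log2 ratio of -1.04, with 4 over 2 and 5 under -2. The parasite list consisted of 867 contigs with the PMAR prefix and 1 other. The PMAR contigs had a median of -6.01, with contigs without reads at the floor, and the list lay below all random lists. Of the PMAR contigs, 855 were higher in the healthy library, none in the diseased one, and 12 met neither rule. PMAR contigs took 0.0379% of the reads of the diseased library and 0.459% of those of the healthy one. PMAR_PMAR019584.1.1, the most abundant, had 82.4 CPM against 81.1.

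**Figure D3:**
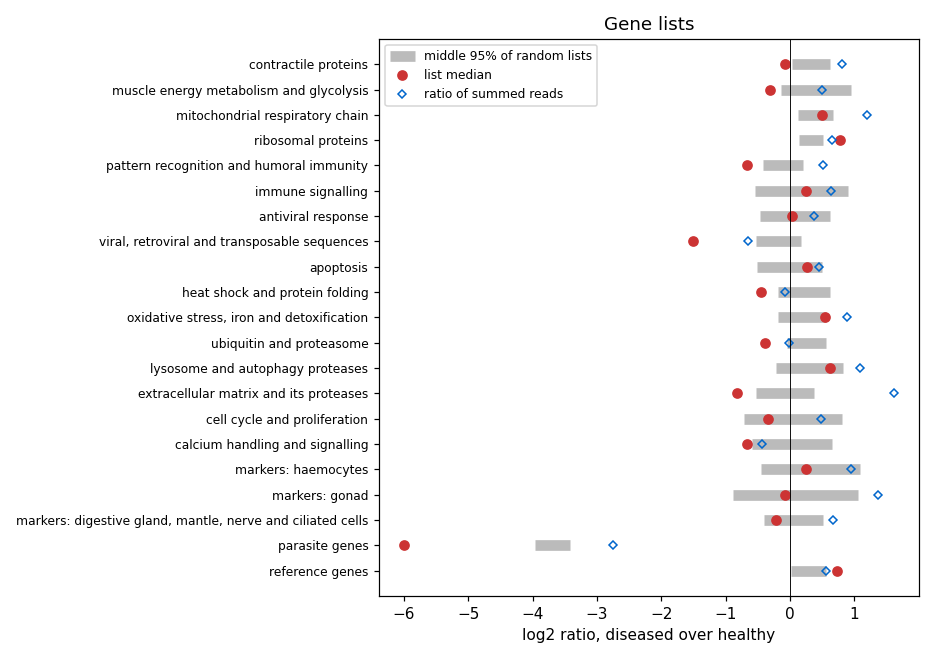
Red points give each list's median log2 ratio of the diseased over the healthy library, grey bars the middle 95% of 10000 random lists matched on expression, and open diamonds the log2 ratio of summed reads. Of the 21 lists, 11 medians lay outside their grey bar, the parasite list farthest down, and the diamonds of 7 lists, the contractile and extracellular matrix lists among them, lie on the other side of 0 from their medians.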

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

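Settings with sums per code, subsets of contigs, single reads, factors from codes, or random lists from named contigs were chosen after seeing the data; the others were planned. Counts of contigs higher in the diseased and healthy library stayed within 1.5 times of 10630 and 13233 under every scaling, minimum and interval rule tried and at 2-fold (8225 to 15388 and 9251 to 18874). They fell to 4181 and 6552 at 16-fold, which is stricter by construction. Smaller sets gave 637 and 2311 per code, 637 and 1473 per code without PMAR, 2029 and 4280 for named contigs, 27 on the healthy side up to the break and 378 on the diseased side after it. Contigs seen in 1 library only stayed within 1.5 times in all 3 alternatives. The median log2 ratio of all contigs was -0.90 with total counts, -0.13 with median of ratios and -0.0215 with factors from codes. Without the 10 most abundant contigs, the top 100 took 21.3% (diseased) and 17.7% (healthy). Lists outside the random range numbered 11, 11 at 100 reads, 10 against named contigs and 5 per code. Of the 11, 5 stayed outside against named contigs, 6 did not and 5 others moved out; per code 4 stayed outside, and 1 other moved out. Relative to all contigs, 6 lists changed sign with summed reads, 1 of them within the random range (cell cycle) and 5 outside it: energy metabolism (0.78), pattern recognition (0.80), heat shock (0.21), ubiquitin (0.27) and extracellular matrix (1.90). Relative to all codes, 8 did so per code, 3 within the random range (antiviral, cell cycle, gonad) and 5 outside it: energy metabolism (1.01), pattern recognition (0.63), ubiquitin (0.18), extracellular matrix (0.44) and calcium handling (0.56). Summed per code, 11 of 86 named contigs changed sign, 7 of them under 4-fold and 4 past it: CNR11.4.4 (1.27), HAAF.9.12 (0.59), LYS.8.15 (1.03) and NCAN.9.9 (0.73). Except where construction shows it, the cause was not tested. No paired analysis was possible because each state has 1 library. Contigs with few reads in a library have wide counting intervals.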

Other observations

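Digestive and shell names, singled out after their values were seen, were among the largest differences per code. The endoglucanase codes GUNA, GUNB and GUNZ had summed log2 ratios of 8.54, 8.10 and 8.03, and the amylase code AMY had 538 CPM in the diseased library against 12.1 in the healthy one. The shell matrix code PLSP had 2801 CPM against 53.3. With TMM factors, ciliary axoneme names differed little in sum, with 279 CPM against 318 (log2 ratio -0.19). Total counts would move that ratio by -0.61. Animal locus tags summed to 8022 against 4821 CPM.

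Codes with contigs called in both directions numbered 435 of the 2417 with more than 1 contig (18.0%). LYS and HAAF were among them.

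In the tests below, those on names with 2 contigs and on alveolate tags were fixed before their results were seen; the others were chosen afterwards, and the one on abundance replaced an earlier test that could not bear on it. The rules for a verdict on the shell and digestive tests were made stricter once their values were known. The change turned the verdicts on the shell tests into undecided ones, as given below. No biological explanation is accepted for any pattern.

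Unnamed contigs leaned to one library by number. A candidate explanation is that the reference joins contigs assembled from each library in turn. It predicts the same order within names, and in 70.5% of 1315 names with 2 contigs (exact interval 67.9 to 72.9) the first contig had the higher ratio. The same order had already been seen in names with more contigs, so the test was not blind to the trend. For an order by abundance, the rank correlation across contigs of number with level reached a size of 0.532 (-0.532, diseased library, all unnamed contigs), between the bounds set for and against it, but lay between -0.113 and 0.0262 within each side of the break, where such an order predicts values near -1 or 1. The disease state itself was not tested against either.

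Most PMAR contigs were far lower in the diseased library, where 480 of 867 had no read. The tables argue against the joined reference as the whole cause: the share of PMAR contigs with a log2 ratio under -5 lay 69.6 points above that of unnamed contigs after the break (85.4% against 15.7%). RNA of an alveolate parasite in the healthy pool was the other explanation. Of 13 contigs with other alveolate tags, 0.0% (exact interval up to 24.7%) lay under -5, which went against it by the bound set beforehand. That bound was weak for some of these contigs, which had too few reads to fall under -5 even without a diseased read. IMG5_089910, with 308 healthy reads, was such a contig. Yet every contig with these tags had reads in the diseased library, so the floor held none of them above -5. The lowest log2 ratio was -3.66, for PFL0290W, with 60 diseased and 1726 healthy reads. Of the 6 names with these tags and 1000 reads or more, 2 had a summed log2 ratio under -2 and 1 over 2. Another weakness seen only afterwards is that contigs from a Perkinsus relative may take PMAR names first, 849 codes here, so other alveolate tags need not share their origin. The source of these contigs was not settled.

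Shell matrix and digestive enzyme names were higher in the diseased library in sum, 22.7-fold and 6.70-fold. Mantle tissue in the muscle sample could add shell transcripts, but 36.4% of 11 shell names with 1000 reads or more had a summed log2 ratio over 2 (exact interval 10.9 to 69.2%), and 5 lay under -2. For digestive tissue the share was 50% of 14 names (exact interval 23% to 77%). By the rules as first written, the shell share counted against mantle tissue and the digestive share decided nothing. The median shell sum of -1.04 met the first prediction of the joined reference. Under the stricter rules that median decides nothing about the joined reference, since its members went both ways. Under those rules these explanations cannot be told apart here, because the names are few and each state has 1 library.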
